A study of Mus musculus with 18 samples.

How the data were processed

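Hearts of C57BL/6 mice aged 12 weeks were profiled by RNA sequencing. Per the labels, the mice were wild-type (WT) or carried a cardiac knockout of Med13 (labelled cKO), and received normal chow, a diet with propylthiouracil (PTU), or the PTU diet followed by triiodothyronine (T3). PTU blocks the synthesis of thyroid hormone, and T3 is the active form of the hormone. The diets started at 8 weeks of age and lasted 4 weeks, and T3 was given as 3 daily injections. Every one of the 18 libraries could be placed in 1 of 6 groups of 3 from its genotype and treatment labels. The labels do not state outright that each library came from a separate animal, so p-values measure the spread between these samples, part of which may be technical. Per the labels' protocols, hearts were frozen in liquid nitrogen, RNA was extracted with Trizol, and polyA libraries were made with a TruSeq kit, version 2, which does not mark the strand.

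The authors deposited gene-level FPKM values (a measure scaled for transcript length and library size), 1 column per library, in a table of 24341 genes. The submitters' processing notes name Bowtie2, Cufflinks and the mouse genome build mm10, without versions; the gene annotation is not given in the sources used here. The authors also deposited 6 tables of pairwise comparisons, which hold, per the file headers, a group value in FPKM for each side, a log2 fold change, a p-value, a q-value and a test statistic (a score). Their log2 column reaches values no expression ratio can take and was not used. From these tables the group values, p-values and q-values were read, and they are named as the authors' wherever they appear. In the FPKM table, 152291 cells stood at a floor of 0.01, and 5532 genes stood at that floor in all 18 libraries. A failed estimate marked 5 cells of 2 genes, Cacna2d1 and Trip10, and both genes were left out of the tests. Spreadsheet software had turned 27 gene symbols into dates; these were kept as they stood and none was named.

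The FPKM values carry no read totals, so the absolute depth is unknown and no counting interval can be given. The steps between low values give relative depth only: over 1932 genes with at most 0.3 FPKM, the deepest library stood 1.53 times above the shallowest, with 30.8% to 38.8% of the ratios in the peak that was read. Strand use in counting was not stated, so reads of a gene and of an overlapping gene on the other strand cannot be told apart. Such overlaps include Myh7 with Mhrt, Thra with Nr1d1, Med13 with Brip1os and Pln with Cep85l. Positions are from the GRCm38 annotation, which is the mm10 assembly, and 12475 of the 12587 tested genes (99.1%) had one.

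Genes with at least 1 FPKM in at least 3 libraries were tested, which left 12587. Values were analysed as log2(FPKM + 1). A fold change on this scale understates the change of genes with low values. A linear model with 6 group means was fitted to all 18 libraries with limma 3.58.1 in R 4.3.3, with a trended prior and robust estimation, on 12 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each of 11 comparisons, and a gene was called at an adjusted p under 0.05 with no minimum fold change. The comparisons were PTU against chow and PTU with T3 against PTU in each genotype, PTU with T3 against chow in WT, cKO against WT on each treatment and averaged over treatments, and the interactions of PTU and of T3 with genotype. Adjusted p-values of single genes throughout come from this limma fit. Errors are standard deviations (SD) of FPKM values or standard errors (SE) of log2 fold changes.

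There were 31 gene lists, fixed before the data were examined, and 30 were tested as sets with limma's camera test at a preset correlation between genes of 0.01, adjusted over lists within a comparison. The list of sex-linked genes was left out of that test. The test was repeated with a correlation estimated from the data. Lists covered genes that thyroid hormone induces or represses in heart, its receptors and transport, Mediator subunits, cardiomyocyte functions, metabolism, stress and immune responses, and markers of other cell types. Genes named in the text were drawn from those meeting a rule set at the same time: a fixed panel with Med13 in every comparison, the 5 highest and 5 lowest called genes without overlap between groups for PTU and for T3 in WT (3 and 3 in the other comparisons), up to 4 called members of each list that was called or had at least 3 called members, and for an interaction without calls the 3 genes with the smallest p. Genes named outside this rule are said to be so.

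The linear model was tested on simulated data with 200 of 12587 genes changed by known amounts, in 10 draws. For PTU against chow in WT it recovered 10.1% of 1.25-fold, 53.3% of 1.5-fold and 87.6% of 2-fold changes. For the averaged genotype comparison it recovered 58.1%, 87.9% and 97.3%, and for the PTU interaction 0.896%, 16.9% and 61.5%. False calls averaged 3.8, 5.3 and 0.4 per draw in these 3 comparisons. The changes were added on the log2(FPKM + 1) scale. The same fold change in FPKM is smaller on that scale for low genes, so their recovery is overstated. Alternatives set in advance were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, median ratio scaling, sample weights, only the compared groups in the fit, and leaving out each replicate in turn. Covariates for matrix and atrial genes, centred within groups or not, and leaving out the heart highest in either score in each group, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.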

Results

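Transcript levels were measured in 18 mouse hearts, 3 in each of 6 groups formed by 2 genotypes (WT and the hearts labelled cKO) and 3 treatments (normal chow, PTU, and PTU followed by T3). Med13 is a subunit of the kinase module of the Mediator complex, and the series concerns its part in how the heart responds to thyroid hormone. Between 11679 and 12093 genes reached 1 FPKM in a library, and the 10 most abundant genes held 12.5% to 17.7% of all FPKM. Pearson correlations between replicates, across genes, lay between 0.975 and 0.992. Genes are not independent replicates. The first principal component held 51.3% of the variance and ordered the hearts by treatment, with PTU hearts between -34.3 and -26.7, chow hearts between -3.51 and 3.70, and T3 hearts between 27.1 and 36.2.

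Med13 itself, the gene named by the genotype label, lies on chromosome 11 from 86267033 to 86357602. Its level was 5.87 ± 0.596 FPKM in WT hearts and 5.83 ± 0.713 FPKM in hearts labelled cKO (SD, n = 9 each), and single libraries ranged from 4.93 to 6.96 FPKM. On chow it stood at 5.52 ± 0.283 FPKM in WT and 5.90 ± 0.702 FPKM in cKO, on PTU at 6.36 ± 0.716 and 5.34 ± 0.618 FPKM, and with T3 at 5.73 ± 0.509 and 6.25 ± 0.723 FPKM (SD, n = 3 each). The averaged log2 fold change was -0.01 (SE 0.0621, adjusted p = 1). The gene-level values therefore do not separate the genotypes, which are called by their labels throughout, and any direction drawn between genotypes rests on those labels. No values per exon were analysed here.

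In WT hearts, PTU exchanged the major myosin heavy chains. Myh6, the fast alpha chain of the adult mouse ventricle (chromosome 14, 54941921 to 54966927), fell from 3204 ± 793 to 239.5 ± 151 FPKM (SD, n = 3; log2 fold change -3.91, SE 0.367, adjusted p = 8.67e-06). Myh7, the slow beta chain next to it (54970684 to 54994626), rose from 136 ± 40.4 to 3110 ± 522 FPKM (log2 fold change 4.53, SE 0.251, adjusted p = 4.30e-08). Reads of its antisense transcript Mhrt cannot be told apart from it. The pacemaker channel Hcn2 fell from 15.2 ± 2.73 to 1.88 ± 0.132 FPKM, and the mitochondrial uncoupling protein Ucp3 from 18.8 ± 6.52 to 2.04 ± 0.404 FPKM. Tnni1, the troponin I of slow skeletal muscle, rose from 0.433 ± 0.232 to 13.5 ± 7.23 FPKM. The comparison asks how the heart's transcripts respond when thyroid hormone synthesis is blocked. limma called 2111 of 12587 genes (16.8%), 1009 higher and 1102 lower on PTU, 229 of them with a log2 change of at least 1 in size. Counts of list members in each comparison are to be read beside its share of all tested genes.

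Among the calls with the largest changes on PTU in WT hearts, Bex1 rose by a log2 fold change of 3.15 (SE 0.406), Gnmt, a glycine methyltransferase, by 2.61 (SE 0.316) and Scgb1c1 by 2.42 (SE 0.336). Slc17a7, a vesicular glutamate transporter, fell by 3.02 on the log2 scale (SE 0.562), and the chemokine Cxcl14 fell by 2.94 (SE 0.262). Acta1, skeletal alpha-actin, fell from 831 ± 644 to 66.0 ± 26.1 FPKM (adjusted p = 0.00244), a call that ended without the heart highest in atrial genes of each group (adjusted p = 0.0637). The receptor gene Thra rose from 29.9 ± 1.17 to 55.8 ± 3.74 FPKM, with overlap by Nr1d1 on the other strand. Atp2a2, the calcium pump of the sarcoplasmic reticulum, stood at 2692 ± 759 FPKM on chow and 1601 ± 428 FPKM on PTU (adjusted p = 0.0702), and its inhibitor Pln at 3033 ± 358 and 4394 ± 677 FPKM (adjusted p = 0.0714). Thrb, Kcnd2, Nppa, Nppb and Med13 were not called, with adjusted p of 0.0709, 0.968, 0.970, 0.572 and 0.297. Thrsp, a regulator of lipid synthesis, fell by 0.65 on the log2 scale (SE 0.203, adjusted p = 0.0387). Its call ended under 8 alternatives, among them leaving out WT chow replicate 1, WT chow replicate 3 or WT PTU replicate 1, with an adjusted p of up to 0.38.

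Of 20 tested genes that thyroid hormone is known to induce in heart, 11 fell and 1 rose on PTU in WT hearts, and 14 fell and 2 rose when adjusted over the list alone. Besides Myh6, Hcn2 and Ucp3, the corepressor gene Hr fell by 2.06 on the log2 scale (SE 0.171). The member that rose was Ppargc1a, a coactivator of mitochondrial genes, named after its values were seen (log2 fold change 1.10, SE 0.247). Its call ended without the hearts highest in matrix genes (adjusted p = 0.0555). The list was called lower by camera (adjusted p = 3.01e-06), but not with an estimated correlation (adjusted p = 0.44 with an estimated correlation). Of 9 genes known to be repressed by the hormone, 6 rose and 0 fell (8 and 0 adjusted over the list alone), including Myh7, Tnni1 and Thra. This list was called at the preset correlation (adjusted p = 4.32e-07) and with an estimated one (adjusted p = 0.0303 with an estimated correlation). It was the only one of 66 list calls over the 11 comparisons that held with an estimated correlation.

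Genes of contraction and excitation moved in both directions on PTU in WT hearts. Of 24 sarcomere genes 5 rose and 4 fell (7 and 4 adjusted over the list alone): Myom2, a protein of the M band, rose from 269 ± 25.3 to 741 ± 120 FPKM, and Actc1, cardiac alpha-actin, fell from 10640 ± 1190 to 4957 ± 346 FPKM. Of 27 ion channel genes 5 rose and 8 fell (7 and 8 adjusted over the list alone), and the sodium channel subunits Scn4a and Scn4b fell by 1.57 and by 2.45 on the log2 scale (SE 0.172 and 0.324). Of 22 calcium handling genes 2 rose and 3 fell (3 and 5 adjusted over the list alone). The L-type channel Cacna1c rose from 26.9 ± 3.40 to 43.2 ± 4.52 FPKM. Of 23 adrenergic and muscarinic signalling genes 3 rose and 5 fell, likewise 3 and 5 adjusted over the list alone. The phosphodiesterase Pde3a rose by 1.17 (SE 0.173), and Rgs4, a regulator of G protein signalling, fell from 8.27 ± 0.868 to 2.93 ± 0.647 FPKM. None of these 4 lists was called by camera.

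Metabolic genes were called in part. Of 36 fatty acid oxidation and lipid genes 1 rose and 6 fell on PTU in WT hearts (1 and 8 adjusted over the list alone): Cpt2, a mitochondrial carnitine acyltransferase, fell from 121 ± 21.7 to 59.4 ± 11.8 FPKM and Angptl4, an inhibitor of lipoprotein lipase, fell from 11.1 ± 5.39 to 1.03 ± 0.362 FPKM. Of 42 oxidative phosphorylation genes 1 rose and 2 fell (0 and 2 adjusted over the list alone), and of 29 glycolysis genes 2 rose and 5 fell (2 and 5 adjusted over the list alone), among them the glycolytic kinase Pgk1, which fell by 0.56 (SE 0.0846). Ddit4, an inhibitor of mTOR signalling, rose by a log2 fold change of 1.61 (SE 0.136). In its stress response list of 24 genes 1 rose and 3 fell, and the same numbers passed when adjusted over the list alone.

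Immune genes were lower on PTU in WT hearts. Of 13 macrophage markers 8 fell and 0 rose (10 and 0 adjusted over the list alone; camera adjusted p = 9.64e-06, adjusted p = 0.838 with an estimated correlation). C1qa, a complement component made by macrophages, fell from 83.0 ± 24.9 to 36.1 ± 9.29 FPKM. The call ended without WT chow replicate 3 or without the hearts highest in atrial genes, with an adjusted p of up to 0.0866. Of 23 interferon response genes 10 fell and 0 rose (15 and 0 adjusted over the list alone; camera adjusted p = 1.85e-06, adjusted p = 0.838 with an estimated correlation), and Gbp3, a guanylate-binding protein, fell from 6.51 ± 0.870 to 1.60 ± 0.146 FPKM. Of 27 cell cycle genes 2 fell (1 adjusted over the list alone; camera adjusted p = 0.00623, adjusted p = 0.954 with an estimated correlation), and Ccnd1, cyclin D1, fell from 18.7 ± 2.21 to 9.28 ± 2.24 FPKM.

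The number of genes called for PTU in WT hearts fell from 2111 to 662 without the heart highest in atrial genes of each group, to 1379 without WT chow replicate 1 and to 1346 without WT PTU replicate 1. Groups did not overlap for 35.6% of tested genes, where chance gives 10%.

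**Figure D1:**
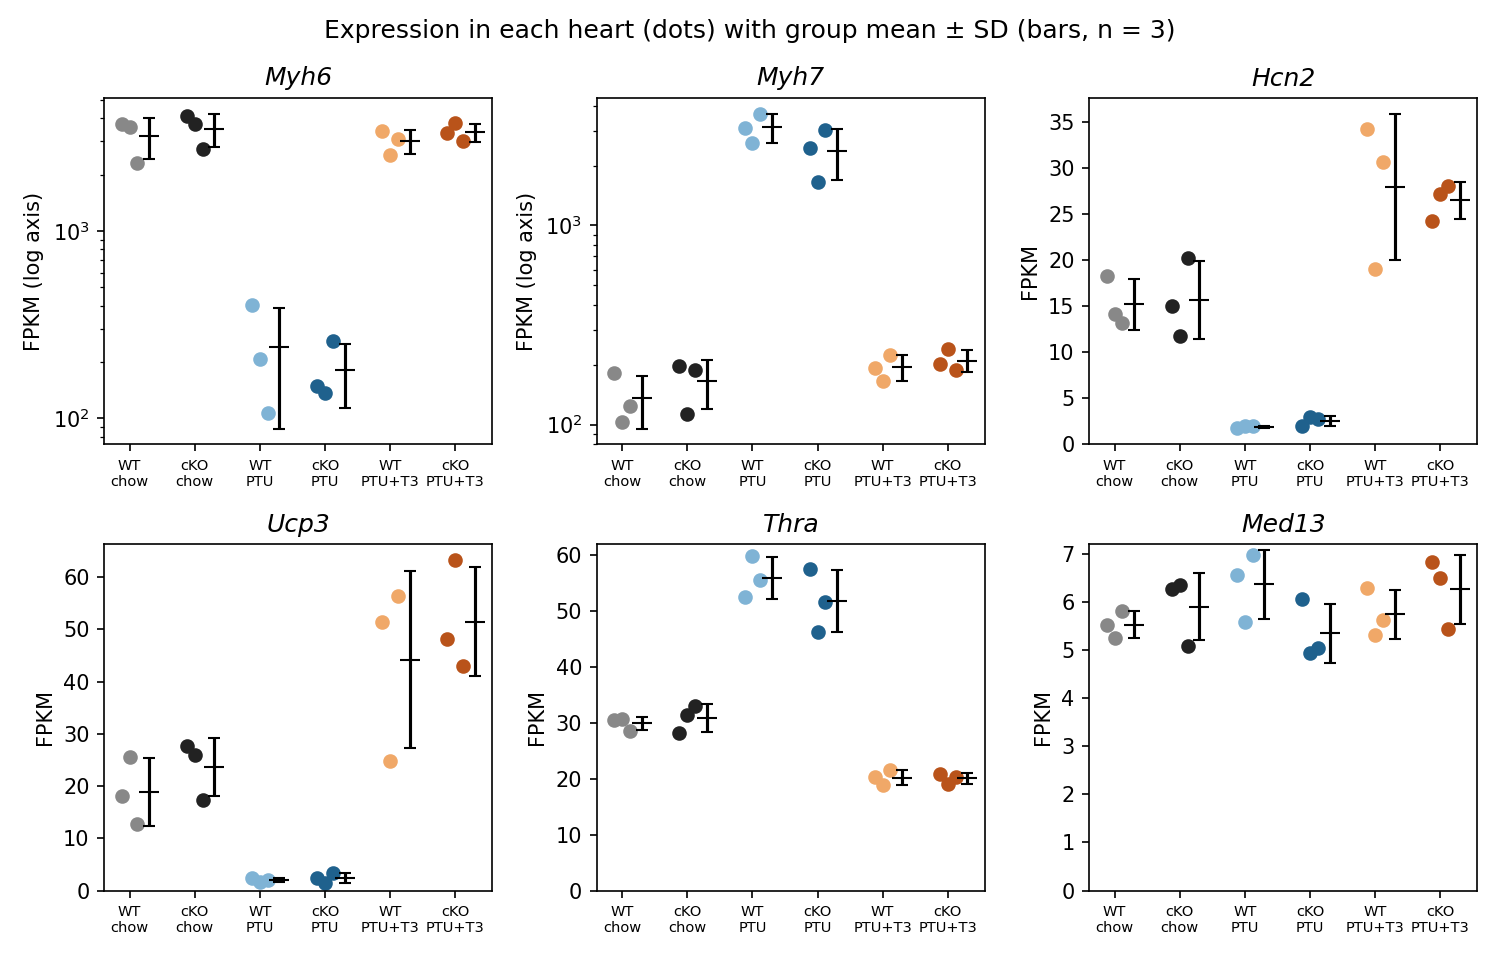
FPKM of Myh6 and Myh7 (log axes) and of Hcn2, Ucp3, Thra and Med13 (linear axes) in each of the 18 hearts, as dots, with the mean and SD of each group of 3 as bars. PTU hearts lie apart from chow and T3 hearts for the first 5 genes, while Med13 lies between 4.93 and 6.96 FPKM in all groups.

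T3 given after PTU to WT hearts brought the myosin chains back. Myh6 rose from 239.5 ± 151 to 3024 ± 445 FPKM (SD, n = 3; log2 fold change 3.85, SE 0.367, adjusted p = 1.21e-06) and Myh7 fell from 3110 ± 522 to 194 ± 29.0 FPKM (log2 fold change -3.99, SE 0.251, adjusted p = 1.50e-08). Hr, on chromosome 14 from 70552212 to 70573548, rose from 0.982 ± 0.550 to 53.1 ± 5.50 FPKM, Hcn2 from 1.88 ± 0.132 to 28.0 ± 7.91 FPKM and Ucp3 from 2.04 ± 0.404 to 44.2 ± 17.0 FPKM. Thra fell from 55.8 ± 3.74 to 20.2 ± 1.36 FPKM, whereas Thrb, the other receptor gene, rose (adjusted p = 4.92e-05). The comparison asks what the hormone changes in hearts depleted of it. limma called 5545 of 12587 genes (44.1%), 2802 higher and 2743 lower, 895 of them with a log2 change of at least 1 in size. Some lists, such as Mediator subunits, had a smaller share of members called.

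The highest calls with T3 in WT hearts were Hr (log2 fold change 4.81, SE 0.171), Klhl33 (4.53, SE 0.259), the ubiquitin ligase gene Trim7 (4.05, SE 0.186), Acta1 (4.02, SE 0.626) and Myh6. The lowest were Myom2, which fell by 4.72 on the log2 scale (SE 0.217), Myh7, Cpxm2, which fell by 3.72 (SE 0.305), Armc2, which fell by 3.34 (SE 0.228), and Kcnip2, a subunit of the transient outward potassium channel, which fell by 3.20 (SE 0.336). Pln fell from 4394 ± 677 to 2242 ± 356 FPKM (adjusted p = 0.000780), and Atp2a2 rose from 1601 ± 428 to 2775 ± 458 FPKM (adjusted p = 0.0218). The Atp2a2 call ended without WT PTU replicate 2, without replicate 1 or 3 of WT with T3, or without the hearts highest in atrial genes, with an adjusted p of up to 0.114. Thrsp rose by 1.42 (SE 0.203). Kcnd2, Nppa, Nppb and Med13 were not called, with adjusted p of 0.938, 0.918, 0.955 and 0.363.

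Of the 20 hormone-induced genes 16 rose and 1 fell with T3 in WT hearts (16 and 1 adjusted over the list alone; camera adjusted p = 2.28e-06, adjusted p = 0.346 with an estimated correlation). The member that fell was Ppargc1a (log2 fold change -1.55, SE 0.247). Atp1b1, a subunit of the sodium pump, rose from 96.2 ± 5.62 to 310 ± 56.7 FPKM. Of the 9 hormone-repressed genes 8 fell and 0 rose (8 and 0 adjusted over the list alone; camera adjusted p = 2.28e-06, adjusted p = 0.0639 with an estimated correlation), among them Tnni1 and Myh7b, which fell by 3.14 (SE 0.308) and by 2.44 (SE 0.254). Of 33 Mediator subunit genes 5 rose and 7 fell, likewise 5 and 7 adjusted over the list alone. Med25 fell from 41.7 ± 1.84 to 24.7 ± 5.19 FPKM and Med12 from 7.96 ± 0.710 to 5.40 ± 0.429 FPKM. Of 14 genes of hormone receptors, transport and metabolism 4 rose and 4 fell (5 and 5 adjusted over the list alone).

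Cell cycle genes rose together with T3 in WT hearts: 23 of 27 rose and 0 fell (24 and 0 adjusted over the list alone; camera adjusted p = 2.07e-09, adjusted p = 0.346 with an estimated correlation). Ccnd1 rose from 9.28 ± 2.24 to 33.8 ± 4.68 FPKM, the replication helicase gene Mcm5 from 0.949 ± 0.347 to 4.61 ± 0.657 FPKM, and Rrm2, a subunit of ribonucleotide reductase, from 0.527 ± 0.291 to 3.73 ± 0.562 FPKM. Macrophage markers rose in the same hearts, 12 of 13 with 0 lower (13 and 0 adjusted over the list alone; camera adjusted p = 4.86e-05, adjusted p = 0.838 with an estimated correlation). Mrc1, the mannose receptor, rose from 5.53 ± 1.90 to 16.9 ± 1.69 FPKM and C1qa from 36.1 ± 9.29 to 111 ± 14.7 FPKM. Of 23 interferon response genes 16 rose and 0 fell (18 and 0 adjusted over the list alone; camera adjusted p = 2.28e-06, adjusted p = 0.715 with an estimated correlation), with Gbp3 rising from 1.60 ± 0.146 to 10.2 ± 3.92 FPKM. Of 15 endothelial markers 2 rose, and 1 rose when adjusted over the list alone.

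Of 36 fatty acid genes 13 rose and 3 fell with T3 in WT hearts, and of 42 oxidative phosphorylation genes 14 rose and 1 fell, with the same numbers adjusted over each list alone. Cpt2 rose from 59.4 ± 11.8 to 171 ± 27.2 FPKM, cytochrome c (Cycs) from 288 ± 54.4 to 688 ± 84.3 FPKM, and lipoprotein lipase (Lpl) fell from 2356 ± 500 to 679 ± 124 FPKM. Of 29 glycolysis genes 7 rose and 11 fell (7 and 12 adjusted over the list alone): Pgk1 rose from 259 ± 15.2 to 816 ± 29.7 FPKM, and the hexokinase gene Hk1 fell by 1.11 on the log2 scale (SE 0.104). Of 24 sarcomere genes 6 rose and 11 fell, and of 27 ion channel genes 9 rose and 10 fell, with the same numbers adjusted over each list alone. The gap junction gene Gja1 fell from 179 ± 13.9 to 68.9 ± 1.87 FPKM. Of 34 collagen and matrix genes 7 rose and 0 fell (5 and 0 adjusted over the list alone), and Col4a2, a basement membrane collagen, rose from 29.3 ± 4.76 to 79.1 ± 13.5 FPKM. None of the lists of this paragraph was called by camera.

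**Figure D2:**
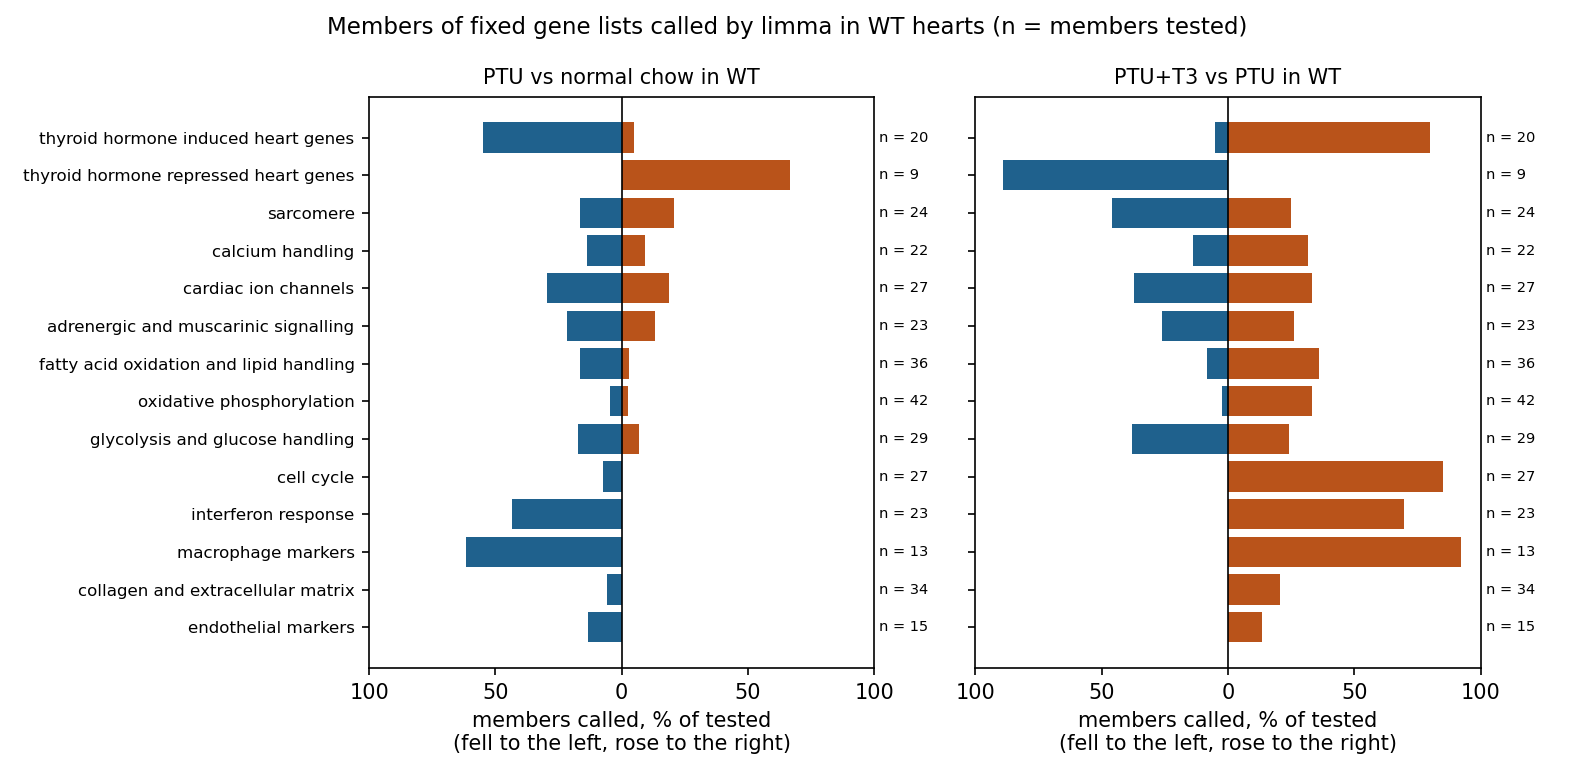
Share of tested members of 14 gene lists called by limma in WT hearts, as percent, for PTU against chow and for PTU with T3 against PTU. Bars to the left are members that fell and bars to the right members that rose. N gives the members tested, and 16 of 20 hormone-induced genes rose with T3.

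Of the 2111 genes called for PTU in WT hearts, 1876 (88.9%) were called in the opposite direction with T3, 881 of the 1009 that had risen and 995 of the 1102 that had fallen, and 0 were called in the same direction. The count moved to 1217 without WT PTU replicate 1, to 603 without the hearts highest in atrial genes and to 2817 with sample weights. Both comparisons share the WT PTU libraries. Independent lists would share 219.9 and 245.3 genes. The correlation of the log2 fold changes across genes was -0.829 against -0.525 in 100 draws of unchanged groups sharing those libraries, and their covariance -0.176 against -0.0171, a difference of -0.159. With no library shared, 1684 of the WT PTU calls (79.8%) were called in the opposite direction for T3 in cKO hearts, where independent lists would share 219.6 and 274.6, and 7 in the same direction. The 3 PTU libraries of a group cannot be split into parts of 2, so part of the excess within WT may come from the shared libraries. Another 3669 genes were called with T3 in WT without a call on PTU.

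Compared with chow, WT hearts given PTU and T3 differed in 1848 genes (14.7% of those tested), 967 higher and 881 lower. Of the 1876 reversed genes, 1322 were not called against chow, 553 lay past the chow level and 1 short of it. Myh6 (3204 ± 793 and 3024 ± 445 FPKM, adjusted p = 0.936) and Myh7 (136 ± 40.4 and 194 ± 29.0 FPKM, adjusted p = 0.163) were not called. Neither were Atp2a2, Pln, Kcnd2, Acta1, Nppa, Nppb and Med13, with adjusted p of 0.888, 0.139, 0.987, 0.574, 0.909, 0.623 and 0.825. Hr lay above chow, at 53.1 ± 5.50 against 7.06 ± 0.947 FPKM, as did Klhl33, at 39.8 ± 7.30 against 5.38 ± 2.37 FPKM, while Myom2, at 27.4 ± 5.86 against 269 ± 25.3 FPKM, Cpxm2, at 1.09 ± 0.256 against 10.9 ± 4.10 FPKM, and Lrrc2, at 19.1 ± 5.61 against 91.3 ± 11.2 FPKM, lay below it. Thra also lay below chow (log2 fold change -0.55, SE 0.0880). Hcn2, Thrb, Ucp3 and Thrsp were called above chow, with log2 fold changes of 0.81, 0.60, 1.16 and 0.77 (SE 0.200, 0.145, 0.308 and 0.203). Each of these 4 calls ended without replicate 3 of WT with T3. Those of Hcn2, Thrb and Ucp3 also ended without WT chow replicate 3, those of Hcn2 and Ucp3 without replicate 1 of WT with T3, that of Ucp3 without WT chow replicate 1, and that of Thrsp without replicate 2 of either group. The adjusted p reached 0.173, 0.178, 0.225 and 0.124.

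Of 27 cell cycle genes 18 stood above chow in WT hearts with T3 and 0 below (25 and 0 adjusted over the list alone; camera adjusted p = 1.98e-13, adjusted p = 0.441 with an estimated correlation). Top2a, a topoisomerase of dividing cells, stood at 3.20 ± 0.753 against 0.605 ± 0.222 FPKM. Of the 20 hormone-induced genes 8 stood higher and 0 lower (8 and 0 adjusted over the list alone; camera adjusted p = 0.000974, adjusted p = 0.78 with an estimated correlation), among them Atp1b1, at 310 ± 56.7 against 136 ± 4.42 FPKM. Of 27 ion channel genes 2 stood higher and 7 lower (2 and 9 adjusted over the list alone), with Kcnip2 at 20.5 ± 10.4 against 81.5 ± 18.5 FPKM. The interferon list was called higher with 0 members called, by either adjustment (camera adjusted p = 0.0283, adjusted p = 0.982 with an estimated correlation). The count of 1848 genes moved to 857 with only the compared groups in the fit, to 1202 and 722 without the hearts highest in matrix and in atrial genes, to 1017 without WT chow replicate 1 and to 949 without replicate 3 of WT with T3.

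In hearts labelled cKO, PTU also exchanged the myosin heavy chains. Myh6 fell from 3514 ± 703 to 181 ± 67.4 FPKM (SD, n = 3; log2 fold change -4.31, SE 0.367, adjusted p = 6.42e-06) and Myh7 rose from 166 ± 45.7 to 2379 ± 682 FPKM (log2 fold change 3.84, SE 0.251, adjusted p = 5.12e-07). Hcn2 fell from 15.7 ± 4.24 to 2.55 ± 0.523 FPKM, Ucp3 from 23.6 ± 5.49 to 2.45 ± 0.957 FPKM and Atp2a2 from 3424 ± 918 to 1143 ± 302 FPKM. Tnni1 rose from 0.520 ± 0.274 to 7.63 ± 2.32 FPKM, and Thra from 30.8 ± 2.45 to 51.7 ± 5.57 FPKM. Acta1 fell by 2.78 on the log2 scale (SE 0.626), a call that ended with only the compared groups or without the hearts highest in atrial genes (adjusted p of up to 0.148). Kcnd2 fell by 0.95 (SE 0.301, adjusted p = 0.0433), a call that ended under 9 alternatives, among them leaving out cKO chow replicate 1 or 2 or any cKO PTU replicate (adjusted p of up to 0.19). Pln, Thrb, Nppa, Nppb, Thrsp and Med13 were not called, with adjusted p of 0.949, 0.0787, 0.168, 0.544, 0.464 and 0.485. limma called 2017 genes (16.0% of those tested), 810 higher and 1207 lower. The count moved to 992 with only the compared groups, to 517 without the hearts highest in atrial genes, and to 955, 1265 and 1255 without cKO chow replicate 1, cKO chow replicate 2 and cKO PTU replicate 1.

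Fatty acid genes were lower on PTU in hearts labelled cKO: 16 of 36 fell and 0 rose (25 and 0 adjusted over the list alone; camera adjusted p = 2.83e-09, adjusted p = 0.881 with an estimated correlation). Cpt2 fell from 136 ± 30.9 to 55.0 ± 7.33 FPKM, Angptl4 from 16.2 ± 4.00 to 1.48 ± 0.795 FPKM and Pdk4, which restrains pyruvate oxidation, from 189 ± 51.3 to 33.3 ± 13.3 FPKM. Of 42 oxidative phosphorylation genes 10 fell and 0 rose (11 and 0 adjusted over the list alone; camera adjusted p = 5.88e-07, adjusted p = 0.881 with an estimated correlation), and Cox7a1 fell from 4013 ± 666 to 1686 ± 377 FPKM. Of the 20 hormone-induced genes 13 fell and 0 rose (16 and 1 adjusted over the list alone; camera adjusted p = 2.83e-09, adjusted p = 0.144 with an estimated correlation), and of the 9 hormone-repressed genes 6 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 4.26e-06, adjusted p = 0.0753 with an estimated correlation). Of 6 erythroid markers 4 fell (4 adjusted over the list alone; camera adjusted p = 0.00126, adjusted p = 0.614 with an estimated correlation), among them Alas2, of haem synthesis, from 30.1 ± 9.62 to 8.66 ± 2.49 FPKM.

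Immune lists were called lower as well on PTU in hearts labelled cKO. Of 23 interferon genes 4 fell and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 0.000530, adjusted p = 0.881 with an estimated correlation), with Gbp3 falling from 6.61 ± 0.691 to 1.85 ± 0.626 FPKM. Of 13 macrophage markers 1 fell (6 adjusted over the list alone; camera adjusted p = 0.00396, adjusted p = 0.881 with an estimated correlation). The largest falls included Baiap2l1, at 50.6 ± 3.55 FPKM on chow and 5.80 ± 0.116 FPKM on PTU. Among the WT chow hearts it stood at 7.42, 7.69 and 42.0 FPKM, so it also differed within a group. Of the 2111 and 2017 genes called for PTU in WT and in cKO, 1066 were shared, 416 higher and 650 lower, with 0 in opposite directions. Independent lists would share 64.93 and 105.7. The fold changes correlated across genes with r = 0.690, against 0.000238 in unchanged groups, and their covariance was 0.0943 against 2.89e-05. The shared count moved to 535 with only the compared groups, to 288 without the hearts highest in atrial genes and to 673 without cKO chow replicate 1.

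T3 after PTU in hearts labelled cKO raised Myh6 from 181 ± 67.4 to 3351 ± 373 FPKM (SD, n = 3; log2 fold change 4.25, SE 0.367, adjusted p = 4.31e-07) and lowered Myh7 from 2379 ± 682 to 210 ± 26.6 FPKM (log2 fold change -3.46, SE 0.251, adjusted p = 5.92e-08). Hr rose by a log2 fold change of 4.65 (SE 0.171), Klhl33 rose from 0.610 ± 0.131 to 43.6 ± 8.99 FPKM and Hcn2 from 2.55 ± 0.523 to 26.5 ± 2.04 FPKM, while Myom2 fell from 601 ± 117 to 23.3 ± 5.10 FPKM and Cpxm2 from 23.1 ± 3.57 to 0.749 ± 0.204 FPKM. Ucp3, Thrb, Atp2a2, Acta1 and Thrsp rose, with log2 fold changes of 3.95, 1.18, 1.42, 2.86 and 0.93 (SE 0.308, 0.145, 0.269, 0.626 and 0.203), and Thra fell by 1.32 (SE 0.0880). Pln fell by 0.49 (SE 0.193, adjusted p = 0.0488), a call that ended under 7 alternatives, among them leaving out replicate 1 or 3 of cKO PTU or of cKO with T3 (adjusted p of up to 0.178). Kcnd2, Nppa, Nppb and Med13 were not called, with adjusted p of 0.117, 0.0615, 0.389 and 0.153. limma called 5877 genes (46.7% of those tested), 3137 higher and 2740 lower. Of these and the 5545 called in WT, 4259 were shared in direction, 2223 higher and 2036 lower, with 2 in opposite directions. Independent lists would share 698.3 and 597.1, and no library is common to both.

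Of 42 oxidative phosphorylation genes 24 rose and 0 fell with T3 in hearts labelled cKO (26 and 0 adjusted over the list alone; camera adjusted p = 1.28e-05, adjusted p = 0.913 with an estimated correlation), with Cycs rising from 266 ± 25.7 to 802 ± 86.1 FPKM and the complex I gene Ndufs4 from 138 ± 21.8 to 326 ± 29.7 FPKM. Of 36 fatty acid genes 19 rose and 3 fell (20 and 3 adjusted over the list alone; camera adjusted p = 0.00279, adjusted p = 0.913 with an estimated correlation). Cell cycle genes rose in 21 of 27 cases and 1 fell (22 and 1 adjusted over the list alone; camera adjusted p = 6.87e-06, adjusted p = 0.903 with an estimated correlation). Ccnd1 rose from 10.4 ± 2.47 to 35.7 ± 0.877 FPKM. Of 13 macrophage markers 9 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.0111, adjusted p = 0.913 with an estimated correlation), and Lyve1 rose from 11.1 ± 3.16 to 36.1 ± 2.97 FPKM. Of the 20 hormone-induced genes 15 rose and 1, Ppargc1a, fell (15 and 1 adjusted over the list alone; camera adjusted p = 2.10e-06, adjusted p = 0.347 with an estimated correlation), and of the 9 hormone-repressed genes 8 fell and 0 rose (9 and 0 adjusted over the list alone; camera adjusted p = 1.77e-05, adjusted p = 0.111 with an estimated correlation).

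**Figure D3:**
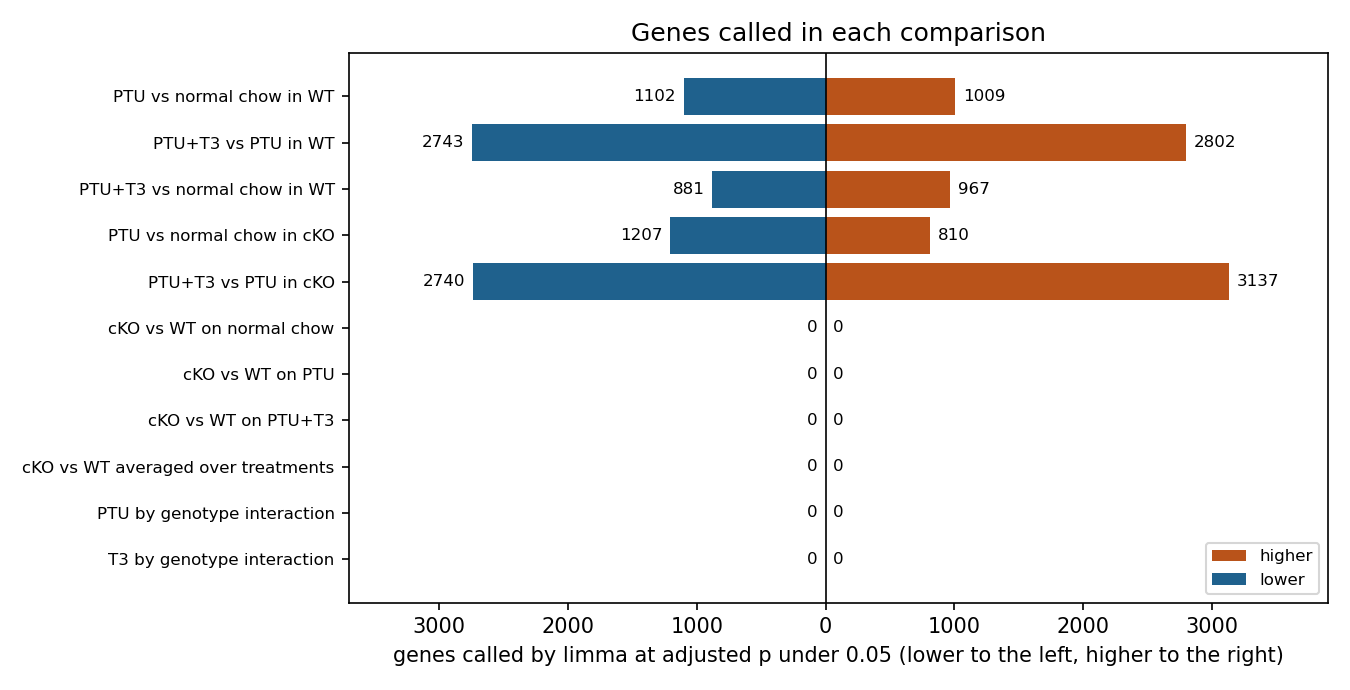
Genes called by limma at an adjusted p under 0.05 in each of the 11 comparisons, lower to the left and higher to the right, as counts. T3 after PTU gave 5545 calls in WT and 5877 in cKO, and the genotype comparisons and interactions gave 0.

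Between genotypes no gene was called by limma, on chow, on PTU, with T3 or averaged over treatments. Unadjusted p fell under 0.05 for 394, 491, 434 and 209 of 12587 genes (3.13%, 3.90%, 3.45% and 1.66%). Each lies below the share of 0.05 that chance alone gives. The comparison asks what the loss of Med13 in cardiomyocytes changes, and it rests on the labels, since Med13 itself did not differ. Myh6 stood at 3204 ± 793 FPKM in WT and 3514 ± 703 FPKM in cKO on chow (SD, n = 3; adjusted p = 0.999), and Myh7 at 3110 ± 522 and 2379 ± 682 FPKM on PTU (adjusted p = 0.911). Med13l, Med12, Cdk8 and Ccnc, the other tested kinase-module genes of the panel, had averaged log2 fold changes of -0.10, -0.04, 0.02 and -0.02 (SE 0.0572, 0.0510, 0.0507 and 0.0613; adjusted p = 1 each). Nppa and Nppb, natriuretic peptides, and Acta1 had -0.25, -0.16 and 0.29 (SE 0.454, 0.368 and 0.361; adjusted p = 1 each). In the authors' group values, differences of Nppa and Nppb changed direction with treatment. Nppa stood at 3622.5 FPKM in WT and 1730 FPKM in cKO on chow, 2923 and 6026 on PTU, and 2746 and 1686 with T3. The authors' tables mark none of these Nppa differences (q-value 0.0876, 0.227 and 0.0811). A single heart stood apart in Nppa among the cKO PTU hearts, as given in the next paragraph. The authors' tables mark Nppb on chow and on PTU (q-value 0.00987 and 0.0212) and Acta1 on PTU (q-value 0.00844), which limma did not call. The 95% interval of the averaged fold change lay within 1.5-fold for 97.1% and within 2-fold for 99.3% of genes. These intervals are on the log2(FPKM + 1) scale, which understates changes of low genes, and they cover only the average over treatments. Groups did not overlap for 8.51%, 7.52% and 8.54% of genes on the 3 treatments, where chance gives 10%.

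Gene lists between genotypes were called only at the preset correlation, with 0 members called by either adjustment. On chow, fatty acid and oxidative phosphorylation genes were called higher in cKO (adjusted p = 8.52e-05 and 0.00761) and matrix genes lower (adjusted p = 0.0265), each with adjusted p = 0.996 with an estimated correlation. WT chow replicate 3 stood apart in matrix genes, with Col1a1, a fibrillar collagen, at 27.1, 23.6 and 66.6 FPKM in the 3 WT chow hearts. On PTU 12 lists were called, each with adjusted p = 0.696 with an estimated correlation. Higher were matrix (adjusted p = 2.12e-06), cell cycle (7.28e-06), interferon (0.00976) and fetal genes (0.0333), and the markers of macrophages (0.000543) and fibroblasts (0.0333). Lower were genes of oxidative phosphorylation (adjusted p = 7.28e-06), the sarcomere (0.000153), fatty acids (0.000153) and glycolysis (0.00498), hormone-repressed genes (0.0268) and erythroid markers (0.000468). In the matrix and macrophage lists cKO PTU replicate 2 stood apart. The 3 cKO PTU hearts had 21.7, 170 and 18.4 FPKM of Col1a1 and 33.9, 83.8 and 38.7 FPKM of C1qa. That replicate also stood apart in the fetal gene Nppa (3206, 10080 and 3955 FPKM) and in the cell cycle gene Aurkb (0.121, 0.862 and 0.055 FPKM). With T3, interferon genes were called lower (adjusted p = 4.39e-14, and adjusted p = 0.469 with an estimated correlation), matrix and fetal genes lower (adjusted p = 3.33e-06 and 0.0212), and oxidative phosphorylation and fatty acid genes higher (adjusted p = 1.81e-07 and 0.0212), the last 4 with adjusted p = 0.965 with an estimated correlation. Of the 3 WT hearts with T3, replicate 2 stood apart in Col1a1 (21.9, 156 and 34.6 FPKM). Replicate 1 stood apart in the interferon gene Gbp3 (14.8, 7.87 and 8.07 FPKM), but not in Bst2 (58.8, 36.9 and 63.2 FPKM) or Rtp4 (5.19, 5.29 and 5.77 FPKM). The genes of this paragraph were chosen after their values were seen. Averaged over treatments only the interferon list was called, lower in cKO (adjusted p = 0.00734, and adjusted p = 0.982 with an estimated correlation). Matrix genes also varied together within groups, with a mean pair correlation of 0.837 over 34 genes.

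The authors' deposited tables mark 80 genes between genotypes on chow, 117 on PTU and 121 with T3. Of these 78, 115 and 116 were tested here and 0 were called. In WT hearts the same tables mark 2062 genes for PTU, of which 1463 of the 2053 tested here were also called, and 4439 for T3, of which 4007 of 4400 were. Among the panel genes, limma called Myh6 and Hcn2 for PTU, which the authors' table does not mark (q-value 0.123 and 0.228). It did not call Thrb and Nppb, which that table marks (q-value 0.00959 and 0.000771). For T3, Hcn2 and Atp2a2 were called here but not marked there (q-value 0.110 and 0.0636). The authors' deposited table gives Med13 group values of 5.51 FPKM in WT and 5.89 FPKM in cKO on chow (q-value 0.999).

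The interactions ask whether the response to PTU or to T3 differed between genotypes, and limma called no gene in either, with 805 and 821 genes at an unadjusted p under 0.05. The genes with the smallest p for PTU, none of them called, were Enkur (log2 difference 1.97, SE 0.377), Lad1 (-1.66, SE 0.332) and Egf (-1.05, SE 0.217), with an adjusted p of 0.739 each. For T3 they were E130218I03Rik (95% interval -1.39 to -0.617, adjusted p = 0.590), B2m, the light chain of class I molecules (-1.30, SE 0.281, adjusted p = 0.696), and Fam220a (0.60, SE 0.131, adjusted p = 0.696). B2m was at 643, 325 and 346 FPKM in the 3 WT hearts with T3, so replicate 1 stood apart. The Myh7 interaction was -0.70 (SE 0.355, adjusted p = 0.764) for PTU and 0.53 (SE 0.355, adjusted p = 0.704) for T3. Med13 had -0.29 (SE 0.152, adjusted p = 0.764) and 0.32 (SE 0.152, adjusted p = 0.696). For both, list calls at the preset correlation had 0 called members, with a smallest adjusted p of 0.853 for PTU and 0.682 for T3 with an estimated correlation.

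**Figure D4:**
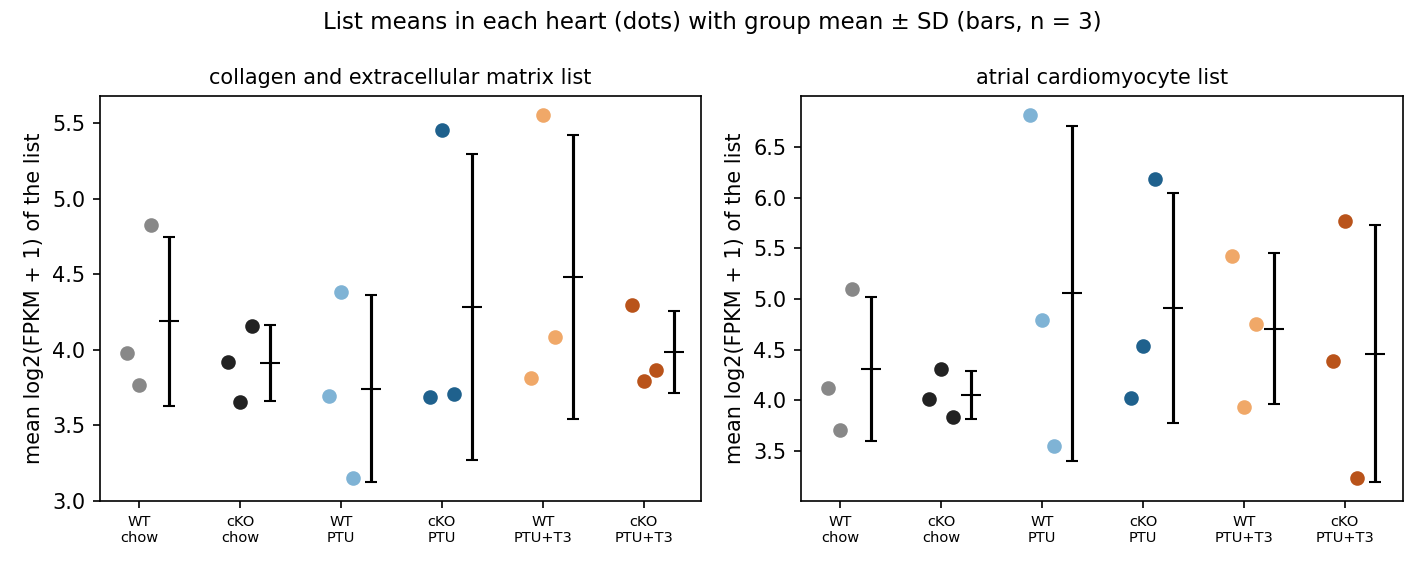
Mean log2(FPKM + 1) over the collagen and extracellular matrix list and over the atrial cardiomyocyte list in each heart, as dots, with the mean and SD of each group of 3 as bars. The highest matrix mean, 5.55, is WT with T3 replicate 2, and the highest atrial mean, 6.82, is WT PTU replicate 1.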

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

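The tests of exchanged labels, of a small deletion, of fibroblast genes, and of covariates on single treatments and in interactions were chosen after the result was seen, as were the covariates for matrix and atrial genes. The permutation tests of Cacna2d1 and Trip10 were not among the tests set before. The other tests of this part were, but the bounds applied for single libraries, strain segments and overlapping genes were stricter than those set. By the set bounds the single-library value would have counted for that explanation, and the values for segments and overlaps against theirs. Stricter readings than the bounds first written were also applied to fibroblast genes, exchanged labels, and covariates on single treatments and in interactions. By the bounds first written, those values would have counted against their explanations.

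Cacna2d1, an auxiliary subunit of the L-type calcium channel, lay outside the tests because failed estimates marked some of its chow libraries. Its level with T3 after PTU was above that on PTU in WT hearts (21.4 ± 0.604 to 59.8 ± 0.910 FPKM; SD, n = 3; 2.80-fold) and in hearts labelled cKO (21.6 ± 2.25 to 64.5 ± 7.02 FPKM; 2.99-fold). The exact two-sided permutation p was 0.1 in each, the smallest that 3 against 3 allows, so this test cannot reach 0.05, and no linear model was fitted to this gene. Trip10, the other gene left out, was lower with T3 in WT hearts (70.8 ± 5.47 to 43.1 ± 6.35 FPKM), with the same permutation p of 0.1. In hearts labelled cKO it stood at 59.8 ± 12.1 FPKM on PTU and 43.9 ± 3.58 FPKM with T3, and no p was computed.

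No gene was called between genotypes, although the authors' deposited tables mark genes there. Matrix and atrial variation as the sole reason is argued against for the averaged comparison only. There 0 genes were called with both scores as covariates, not centred within groups, and the median SE went from 0.0714 to 0.0654. The other comparisons also had 0 calls, with a median SE on PTU going from 0.124 to 0.116, but this cannot decide. For the PTU interaction only 16.9% of simulated 1.5-fold changes were recovered. Covariates centred within groups gave 3 calls on PTU, 2 with T3, and 16 and 38 in the interactions. Of the interaction calls, 9 and 23 were not on the matrix list. Some of these are matrix genes that the list omits. Examples, named after their values were seen, are Ltbp2 and Adamts2 for PTU and Col16a1, Col9a2 and Loxl3 for T3. The numbers off the list are therefore no count of genes apart from matrix variation. Single libraries behind the deposited marks cannot be told apart from other sources. Values did not overlap for 20.1% of the 309 marked genes tested here (20.5% on chow, 13% on PTU, 26.7% with T3). Among unselected genes chance gives 10%, but the authors' test picked these genes on the same libraries, so a higher share is built in. A single library stood at least 2 times above all others for 17.9%, 55.7% and 51.7% of them. That share was not computed over all tested genes. Exchanged labels cannot be told apart from correct ones: the lowest Med13 value among libraries labelled WT was 93.4% of their median, but no library labelled cKO is low either, so the gene cannot show an exchange. A deletion too small to change the gene-level value (averaged log2 fold change -0.01, -0.011 before rounding) also cannot be told apart without values per exon, and the knockout itself stays open as a biological difference.

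Matrix genes varied together between hearts of one group: 34 genes had a mean pair correlation of 0.837 within groups, where the highest of 1000 random sets had 0.096. Atrial tissue is argued against, with a Spearman rho of -0.0361 between the scores over 18 hearts (permutation p = 0.914; Pearson r = -0.0928, permutation p = 0.771; 0.11 without the 2 farthest hearts). More fibroblasts cannot be told apart: per log2 unit of the matrix score, 5 fibroblast identity genes had a median slope of 0.174, all 11 markers a mean of 0.464, and the 8 outside the matrix list a mean of 0.325 and a median of 0.201. Library content stays open, since the rho with the number of genes at the floor was -0.542 (permutation p = 0.0402, 0.0804 adjusted over both relations; Pearson r = -0.558, permutation p = 0.0447; -0.55 without the 2 farthest hearts). No other biological explanation was tested.

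A set of 12 genes had 2 separate levels among hearts of the same group in at least 3 groups: Atp6v0c-ps2, Hba-a2, Hbb-bs, Mir8091, Mir8098, Postn, Ptprn2, Snhg9, Snora23, Snora74a, Snora81 and Stbd1, named after their values were seen. The low level of Hbb-bs, Mir8091, Mir8098, Snhg9, Snora23, Snora74a and Snora81 was the floor of 0.01 FPKM. Atp6v0c-ps2, Hba-a2 and Ptprn2 had low means of 0.0125, 0.0456 and 0.0733 FPKM. Whether these values reflect low expression was not tested. Hba-a2 and Hbb-bs are also on the erythroid list. Stbd1, a glycogen-binding protein, averaged 0.688 FPKM in 6 hearts and 14.6 FPKM in 12. Postn, a matrix gene, was high in the 4 hearts with the highest matrix deviations (0.635, 0.642, 1.07 and 1.17). It is on the matrix list from which these deviations are computed, so it is part of the preceding pattern and no separate evidence for it. Segments of another strain cannot be told apart from other sources, because 0 pairs lay within 5 Mb and random sets gave a median of 0. Reads assigned between overlapping genes stay open as well: 33.3% of these genes overlapped another, against 37.8% of all tested genes, with a 95% exact interval of 9.92% to 65.1%. No other biological explanation was tested.

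For each treatment comparison, 1 of the 10 splits of its 6 hearts gave as many genes as the real one, which was the real split itself, and the highest other split gave 0 genes beside real values of 2111, 5545, 1848, 2017 and 5877. With 10 splits no share under 0.05 can be reached. Every other split also mixes hearts of both treatments in each group, so a treatment difference adds to the spread and lowers the calls. The value of 0 in the other splits was therefore likely from the start and is no measure of chance. The genotype comparisons and interactions had a real value of 0, which every split reaches (10 of 10 on each treatment, 100 of 100 for the others), so these splits carry no information on chance. The highest other split gave 1, 3 and 3 genes on chow, on PTU and with T3, 4 for the averaged comparison, and 3 and 12 for the PTU and T3 interactions.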

How the results depend on the processing

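Covariates for matrix and atrial genes, centred or not, and leaving out the heart highest in either score in each group, were chosen after seeing the data. The 5 treatment counts stayed within 1.5 times of 2111, 5545, 1848, 2017 and 5877 under a pseudocount of 0.1, no filter, a mean of at least 5 FPKM and median ratio scaling. Sample weights moved the PTU count in WT to 3438 and the reversed genes to 2817. With only the compared groups, T3 against chow in WT moved to 857, PTU in cKO to 992 and shared PTU calls to 535; fewer samples estimate the spread there. Without the hearts highest in atrial genes, PTU in WT moved to 662, T3 against chow to 722, PTU in cKO to 517, reversed genes to 603 and shared calls to 288, and without those highest in matrix genes T3 against chow moved to 1202; each fit has 6 fewer hearts. Genotype counts of 0 became, with no filter, 2 on chow (Actl7a, 2900060B14Rik), 4 on PTU (Spata45, Gm5294, Gm21992, Tepp), 1 with T3 (1700030M09Rik), 2 averaged (Spata45, Actl7a), 3 for the PTU interaction (Spata45, Gm5294, Tepp) and 1 for the T3 interaction (Spata45), genes under the filter; the cause was not tested. With covariates centred within groups, which leave the difference between groups unadjusted, they became 3 on PTU (Col1a2, Col5a2, Col15a1), 2 with T3 (Col5a2, Col1a2), and 16 and 38 for the interactions. All of those on PTU and with T3, 7 of the 16 and 15 of the 38 are matrix list genes, from which the score itself is built, and with covariates not centred all 6 counts were 0 and the treatment counts stayed within 1.5 times. Without the hearts highest in matrix genes they became 3 on chow (Baiap2l1, Gm11627, Cenpf), 1 with T3 (Snord17), 1 averaged (Baiap2l1) and 8 for the PTU interaction. On chow the WT heart left out was replicate 3, the highest of its group for Baiap2l1. The log2 fold change of that gene moved from 1.81 to 2.56. The cause of these calls was not tested. The genes of this paragraph were named after their values were seen. Leaving out each replicate gave 1346 to 1787 genes for PTU in WT (1379 without chow replicate 1, 1346 without PTU replicate 1), 4732 to 5063 for T3, 949 to 1752 for T3 against chow (1017 without chow replicate 1, 949 without T3 replicate 3), 955 to 1942 for PTU in cKO (955, 1265 and 1255 without chow replicate 1, chow replicate 2 and PTU replicate 1), 4957 to 5440 for T3 in cKO, 1217 to 1856 reversed (1217 without WT PTU replicate 1) and 673 to 1082 shared (673 without cKO chow replicate 1). Genotype counts ranged from 0 to 1 on chow (Spink4 without cKO replicate 3), 0 to 1 on PTU (Ssbp2 without cKO replicate 3), 0 to 0 with T3 and averaged, 0 to 2 for the PTU interaction (Spink4 and Enkur without cKO chow replicate 3) and 0 to 1 for the T3 interaction (E130218I03Rik without cKO PTU replicate 1). Of 66 list calls, 1 held with an estimated correlation. Of 454 values of named genes 358 were called, 243 kept the call under every alternative run, 115 lost it in at least 1, and 0 reversed. No paired analysis was possible because the labels give no replicate numbers shared between groups. Absolute depth is unknown, so no limit of detection can be given.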

Other observations

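Of the alternatives in this part, only leaving out the hearts highest in matrix genes was chosen after the result was seen.

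Some stress and immediate early genes were also called in WT hearts with T3 after PTU, beside 44.1% of all tested genes. Of 15 immediate early genes 4 fell and 0 rose (3 and 0 adjusted over the list alone), and the nuclear receptor gene Nr4a1 fell from 22.5 ± 2.76 to 3.07 ± 1.23 FPKM (SD, n = 3). Of 24 stress response genes 9 rose and 3 fell (11 and 3 adjusted over the list alone), and Ddit4 fell from 81.3 ± 5.72 to 31.3 ± 4.66 FPKM. Of 22 heat shock and oxidative stress genes 9 rose and 5 fell (10 and 5 adjusted over the list alone): the quinone reductase Nqo1 fell from 56.3 ± 9.92 to 18.1 ± 1.87 FPKM, and Srxn1, a sulfiredoxin, rose from 9.53 ± 1.12 to 22.0 ± 2.46 FPKM. Of 16 glucocorticoid and fasting genes 3 rose and 7 fell (4 and 7 adjusted over the list alone), with Klf15 falling from 52.0 ± 8.77 to 17.6 ± 4.04 FPKM, and of 19 clock genes 2 rose and 7 fell, likewise 2 and 7 adjusted over the list alone, and Cry2 fell by 0.53 on the log2 scale (SE 0.0929). None of these lists was called by camera.

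Further lists were counted for T3 in WT hearts. Of 20 fetal and stress genes 4 rose and 4 fell, of 22 calcium handling genes 7 rose and 3 fell (8 and 4 adjusted over the list alone), and of 23 adrenergic genes 6 rose and 6 fell. The calcium channel Cacna1c fell from 43.2 ± 4.52 to 15.7 ± 2.08 FPKM. Of 12 smooth muscle and pericyte markers 1 rose and 2 fell, of 11 fibroblast markers 1 rose and 1 fell, of 7 fat markers 1 rose, of 4 skeletal muscle and lung markers 2 rose, and of 6 Schwann cell and epicardial markers 2 fell, with the same counts adjusted over each list alone. Of 11 atrial markers 1 fell, and 0 when adjusted over the list alone. None of 5 lymphocyte and neutrophil markers or 6 erythroid markers was called. Of 4 sex-linked genes tested 1, Eif2s3y, named after its values were seen, rose (log2 fold change 0.57, SE 0.186, adjusted p = 0.0213). Without WT PTU replicate 1 its log2 fold change was 0.28 (adjusted p = 0.115), and the call also ended without replicate 2 or 3 of WT with T3 (adjusted p = 0.0779 and 0.0702), with only the compared groups (adjusted p = 0.116) and without the hearts highest in matrix genes (adjusted p = 0.12). The labels give no sex. In all 18 libraries Xist lay between 0.0475 and 0.267 FPKM and Ddx3y between 18 and 33.7 FPKM.

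Atrial genes differed widely within groups. Myl7, the atrial myosin light chain, stood at 1075, 119 and 20.1 FPKM in the WT PTU hearts and at 22.9, 49.2 and 799 FPKM in the cKO PTU hearts, and Sln, sarcolipin, at 497, 61.1 and 5.18 FPKM and at 16.8, 39.3 and 478 FPKM in the same hearts. Both genes were named after their values were seen.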
